A study of Mus musculus with 13 samples.

How the data were processed

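Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed in 13 mouse libraries, 1 library for each of 13 groups. The input and the hemogenic endothelium libraries came from 129P2/OlaHsd ES cells that carry a doxycycline-inducible, HA-tagged RUNX1. Hemogenic endothelium was grown from Flk-1-positive cells sorted from embryoid bodies at day 3.25, with a final culture of 2 days, and induction used 0.3 µl/ml doxycycline overnight, in the unit the labels give. The c-Kit libraries came from progenitors made from another ES line, E14. No group had a replicate, so no p-value was computed between groups.

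The deposited files hold aligned reads, 1 line per read, with 4 columns: chromosome, start, end and strand. They hold no signal values and no peak lists. Per the submitters' processing notes, the tools were Bowtie 0.12.7 and MACS 1.4.2 and the build was mm9. The settings of the alignment, the handling of duplicates and the peak lists were not given in the sources used here. The units of the deposited start and end columns are positions on mm9, and chromosome 1 positions reached 197194472. In all 13 deposited files, forward lines spanned 200 bp from the read start. Reverse lines carried the constant 200 in place of an end, and their start lay 200 bp to the left of the read. This offset was checked on the mitochondrial genome, where the furthest start was 16263 on forward lines and 16263 on reverse lines after 200 bp had been added. Read ends were rebuilt from this rule with a read length of 36 bp, the distance from that start to the end of the mitochondrial genome. Without the correction, reverse reads would fall 200 bp from their true place and every site would be blurred.

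From the deposited reads, 1 read was kept per chromosome, read start and strand. The 237750791 lines gave 219118194 distinct nuclear reads. Distinct reads per library ranged from 1302187 (uninduced anti-HA) to 24441038 (c-Kit FLI1), and the ES input held 3385019. Lines removed as duplicates ranged from 1.16% in the input to 16.6% in the induced H3K9Ac library. Reads were moved 75 bp toward their 3' end. Sites of HA-RUNX1, FLI1, SCL, C/EBPβ and Pol II were called in windows of 200 bp every 50 bp. A window passed at a Poisson p of at most 1e-07 and at least 4-fold over the largest of 3 means: the genome-wide mean, the library's own mean over 10 kb and the scaled input's mean over 10 kb. Windows within 200 bp were merged, and the window with the most reads was the site. H3K9Ac regions, and Pol II regions, used windows of 1000 bp every 200 bp without the library's own 10 kb mean. Sites in merged windows called without a control at p of at most 1e-05 in the input (393) or, for the other libraries, in the uninduced anti-HA library (1595) were left out.

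For each pair of induced and uninduced libraries, distinct reads were counted in 400 bp around the union of sites, or in whole H3K9Ac regions, and scaled to the library's distinct reads (RPM, reads per 1e+06 distinct reads). A site was called higher or lower in the induced library when the ratio was at least 2-fold and its exact 95% interval (Clopper-Pearson, on the split of the reads) excluded 1. All other sites of the union form the class "other". This rule compares 2 libraries, not 2 conditions, and its log2 ratios carry a pseudocount of 0.5 reads. Shares of sites have exact binomial 95% intervals. Reads amplified by PCR without molecular identifiers are not independent molecules and sites are not replicates, so all intervals cover counting error only. Sites of different libraries were joined when their centres lay within 200 bp. Chance overlap was taken from 1000 random shifts of 100 kb to 1 Mb along each chromosome, with 200 shifts for the joint overlap of 5 libraries. Read level, the mean RPM of the induced and uninduced library, was matched in 20 bins with 1000 draws of sites of class "other". For median ratios, 10000 random lists of the same size and level were drawn.

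Calling and classes were tested on simulated libraries of the real depths with 3000 planted sites, of which 200 were changed. In the simulated FLI1 comparison, 48 of 50 sites changed 5-fold and called, 34 of 47 changed 3-fold, 17 of 48 changed 2-fold and 2 of 47 changed 1.5-fold received the right class, over 2745 called sites. Of the unchanged sites in that comparison, 98.4% of 2553 stayed in class "other". In the simulated SCL comparison (2655 sites) the right class went to 46 of 48 sites changed 5-fold and 18 of 44 changed 2-fold. In the simulated HA-RUNX1 comparison (2147 sites), which has the shallow uninduced library, 16 of 36 sites changed 5-fold and 2 of 32 changed 3-fold were classed correctly. In the simulated H3K9Ac comparison (2460 regions) it was 44 of 44 regions changed 5-fold, and the interval held the planted fold in 14 of these. The simulated libraries had a uniform background, Poisson counts and no common shift between libraries. These rates therefore need not hold for the real pairs. Sites chosen for a high or low ratio were not simulated, and their ratios can be too extreme. Background reads were not subtracted, which moves ratios toward 1, so a fold can also be too small. For planted 5-fold changes the interval held the fold at 42 of 50 FLI1 and 38 of 48 SCL sites.

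The rules and most alternatives were set before the data were examined. Alternatives changed the p threshold, duplicates, the read shift, the control, the scaling, the fold rule, the depth and the overlap distance. Named sites follow a fixed rule: in each class of each pair the 3 with the most reads in the library where they were higher, the 5 strongest HA-RUNX1 sites and the 3 strongest C/EBPβ and Pol II sites. This ranking was not corrected for read density by chromosome. Outside called sites the hemogenic endothelium libraries had a raised density on chromosomes 8 and 14, so sites there can rank higher. The gene annotation at hand is of another build (GRCm38), so sites are given by mm9 position, and planned counts at promoters of gene lists and of motifs in sites were not run. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.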

Results

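RUNX1 is a transcription factor needed for blood cells to emerge from hemogenic endothelium. The libraries ask where induced RUNX1 binds in hemogenic endothelium, and how FLI1 (an ETS factor), SCL/TAL1 (a basic helix-loop-helix factor) and H3K9 acetylation (a mark of active promoters and enhancers) are distributed before and after its induction. HA-tagged RUNX1, FLI1, SCL and H3K9Ac were each profiled in 1 induced and 1 uninduced library. C/EBPβ and RNA polymerase II were profiled in uninduced cells, FLI1 and SCL also in c-Kit progenitors, and 1 ES cell input served as control. Distinct reads were 15558031 and 1302187 for induced and uninduced anti-HA, 21662507 and 21048870 for FLI1, 21796092 and 8711848 for SCL, and 22214447 and 23078255 for H3K9Ac. C/EBPβ had 7452895, Pol II 24376517, c-Kit FLI1 24441038 and c-Kit SCL 24090488. There are no replicates.

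Induced HA-RUNX1 occupied 46293 sites. Anti-HA reads at these sites were 3.39-fold higher in the induced than in the uninduced library (95% interval 3.36 to 3.42), and 6.78-fold higher (6.48 to 7.09) at the 1000 sites with the most reads. The pooled ratio was 2.80 with sites of the control libraries kept and 5.59 at the sites called at equal depth, so it depends on which sites enter by more than its interval. The sites held 11.3% of the induced, 3.32% of the uninduced and 1.88% of the input reads. By the site rule, 5988 sites were higher and 18 lower in the induced library. Leaving out sites called in the uninduced anti-HA library removes sites that could be lower, and with control sites kept 6028 were higher and 257 lower. The other 40287 were in neither class, at a median of 1 uninduced read per site. Setting the median ratio to 1 gave 307 higher and 867 lower, a scaling that removes the common change at sites which were all defined in the induced library. The 1000 sites with the most reads and the strongest sites below were taken after control sites were left out. Since these include sites called in uninduced anti-HA, their removal can raise the ratios. The strongest site, on chromosome 8 from 11223051 to 11223450, had 327 induced and 1 uninduced reads, a 27.4-fold ratio (4.88 to 1084). On chromosome 3, the site from 121825801 to 121826200 had 326 and 4 reads (6.82-fold, 2.64 to 25.2). A site on chromosome 8 from 87227301 to 87227700 had 320 and 1 reads (26.8-fold, 4.77 to 1061). Sites on chromosome 7 from 19901851 to 19902250 and on chromosome 14 from 20804301 to 20804700 had 310 and 301 induced reads against 4 and 2 (6.49-fold, 2.51 to 24.0, and 12.6-fold, 3.46 to 104).

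The uninduced anti-HA library was not free of signal at these places. Its reads at HA-RUNX1 sites exceeded the input 1.77-fold (1.75 to 1.79), and 2.34-fold (2.20 to 2.49) at the 1000 strongest. It gave 713 called sites, and 685 of them (96.1%, 94.4 to 97.4) lay within 200 bp of an induced site before control sites were left out, against a mean of 1.17% in random shifts. At equal depth, 2942 induced and 726 uninduced sites were called with control sites kept, and 265 of the uninduced ones (36.5%, 33.0 to 40.1) lay at an induced site.

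Most HA-RUNX1 sites carried no call of another factor before induction. Of the 46293 sites, 37084 (80.1%, 79.7 to 80.5) had no uninduced FLI1, SCL, C/EBPβ, Pol II or H3K9Ac call, and 9209 (19.9%, 19.5 to 20.3) had at least 1, against a mean of 1.85% in random shifts. Uninduced FLI1 was called at 9.79% of HA-RUNX1 sites, SCL at 4.49%, C/EBPβ at 4.11% and Pol II at 9.12%, and 10.6% lay in uninduced H3K9Ac regions. After induction, FLI1 was called at 10.2% of them (9.89 to 10.4) and SCL at 16.0% (15.7 to 16.3), and 21.0% lay in H3K9Ac regions. Among sites with no uninduced call, 4280 had an induced SCL call and 1799 an induced FLI1 call. Seen from the other libraries, 20.8% of uninduced and 40.3% of induced FLI1 sites, and 20.4% of uninduced and 40.1% of induced SCL sites, lay at an HA-RUNX1 site. Of H3K9Ac regions, 52.8% of uninduced and 51.9% of induced ones held an HA-RUNX1 site, so the rise from 10.6% to 21.0% above goes with the larger number of induced regions (16989 against 8645). Depth limits the SCL shares, since the induced SCL library was the deeper of its pair.

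FLI1 reads were lower in the induced library at most sites and higher at a smaller set. At full depth 21754 sites were called in the uninduced and 11673 in the induced library, and at equal depth 21754 and 11318. Over the union of 25665 sites, 2417 were higher and 14001 lower in the induced library, with a median log2 ratio of -1.11. Relative to that shift, with the median ratio set to 1, 4820 sites were higher and 2334 lower. Higher sites had a median of 28 induced and 7 uninduced reads, and lower sites 15 and 44. With 2 libraries, the common shift cannot be assigned to the cells or to the precipitations.

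FLI1 sites that were higher lay at HA-RUNX1 sites far more often than the others. The share was 69.9% (68.0 to 71.7) of higher sites, 26.2% (25.3 to 27.1) of other sites and 18.4% (17.8 to 19.1) of lower sites. Other sites matched on read level to the higher ones gave 18.9% (17.3 to 20.5), and those matched to the lower ones 31.8% (31.1 to 32.5). With the median ratio set to 1 the shares were 54.0%, 20.7% and 10.4%. Random shifts gave a mean of 1.05% for higher sites. FLI1 sites with HA-RUNX1 had a median log2 ratio of -0.67, above all 10000 random lists matched on level, whose 95% range was -1.17 to -1.12. Higher FLI1 sites were less often at uninduced Pol II (2.03%, against 16.4% of level-matched sites) or in uninduced H3K9Ac regions (1.45%, against 14.7%). With the median ratio set to 1 these were 7.82% against 24.3%, and 6.20% against 22.6%. In induced H3K9Ac regions the gap was smaller, with 19.3% of higher FLI1 sites against 27.4% of level-matched ones. More regions were called in the induced library (16989 against 8645), so this need not mean a larger rise of H3K9Ac at higher sites. With classes at a median FLI1 ratio of 1, H3K9Ac reads at higher sites were 2.51-fold higher in the induced library with HA-RUNX1 and 2.11-fold without it. At other sites they were 3.15-fold and 2.63-fold higher, without matching on level. C/EBPβ was called at 6.08% of higher, 8.33% of other and 6.76% of lower FLI1 sites, and with the median ratio set to 1 at 8.24%, 7.17% and 5.96%, so its order by class depends on the scaling. Induced SCL was called at 53.1% of higher FLI1 sites, against 25.2% of level-matched ones, and uninduced SCL at 4.39% against 15.4%. An excess at higher FLI1 sites was thus not particular to HA-RUNX1 among the calls from induced cells.

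Among the named higher FLI1 sites, chromosome 1 from 166065501 to 166065900 had 170 induced and 49 uninduced reads (3.37-fold, 2.44 to 4.73) and an HA-RUNX1 site. Chromosome 13 from 112853801 to 112854200 rose 7.21-fold (4.45 to 12.3) and also had one. Chromosome 14 from 71176201 to 71176600 rose 9.02-fold (5.19 to 17.0), with 169 anti-HA reads in induced cells but no HA-RUNX1 site within 200 bp. Sites counted as without HA-RUNX1 can therefore hold many anti-HA reads. The named lower sites had no HA-RUNX1 site. They lay on chromosome 8 from 87223776 to 87224175 (0.495, 0.430 to 0.569), chromosome 19 from 37510051 to 37510450 (0.219, 0.178 to 0.267) and chromosome 14 from 121564051 to 121564450 (0.360, 0.299 to 0.430).

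**Figure D1:**
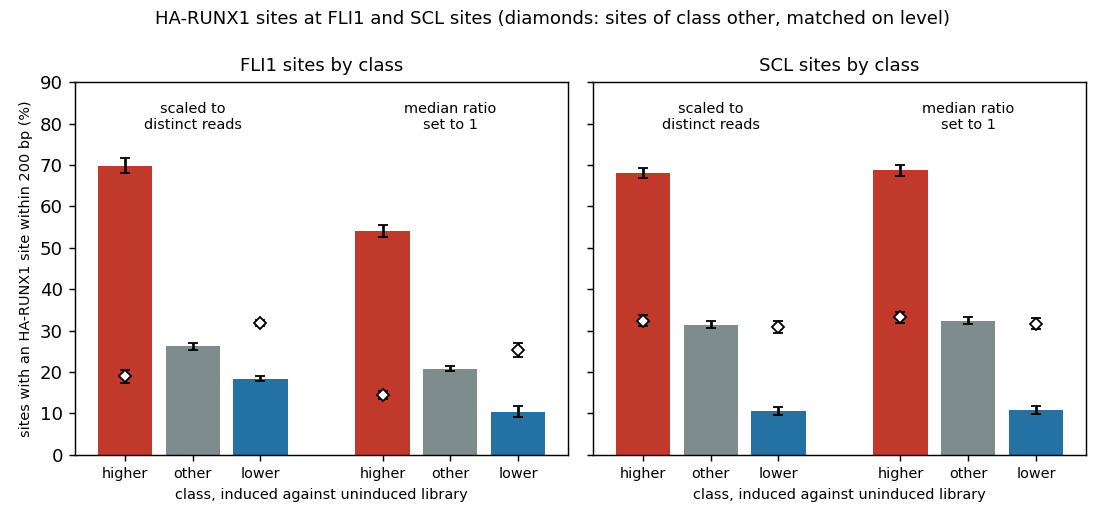
Percent of FLI1 and SCL sites with an HA-RUNX1 site within 200 bp (vertical axis), by class of the site in the induced against the uninduced library and by scaling. Bars are shares with exact 95% binomial intervals, and diamonds are sites of class "other" matched on read level with the 95% range of 1000 draws. Higher sites reach 69.9% for FLI1 and 68.1% for SCL under scaling to distinct reads, and stay above their matched sites under both scalings.

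SCL reads were higher at one set of sites and lower at another after induction. Over 21731 sites, 5108 were higher and 4168 lower in the induced library, with a median log2 ratio of 0.05. In the union of sites called at equal depth, 3044 were higher and 4168 lower, with a median of -0.50, so the sign of the median depends on the depth of the calls. An HA-RUNX1 site was present at 68.1% (66.8 to 69.4) of higher, 31.5% (30.6 to 32.3) of other and 10.5% (9.59 to 11.5) of lower SCL sites. Level-matched other sites gave 32.3% (31.1 to 33.7) for the higher and 30.8% (29.5 to 32.2) for the lower class. SCL sites with HA-RUNX1 had a median log2 ratio of 1.09 and those without one -0.39. The 95% range of random lists matched to the sites with HA-RUNX1 was 0.13 to 0.21. Uninduced Pol II was called at 2.70% of higher SCL sites and 23.6% of level-matched ones, uninduced H3K9Ac at 2.70% and 21.8%, and uninduced FLI1 at 8.93% and 39.8%. Induced H3K9Ac was called at 17.4% and 32.7%, and induced FLI1 at 27.2% and 24.4%. The title of the induced SCL sample carries the suffix of untreated cultures, and its description and treatment labels, which name induction, were followed.

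The named higher SCL sites all had an HA-RUNX1 site. They lay on chromosome 14 from 55324651 to 55325050 (2.46-fold, 1.90 to 3.24), chromosome 10 from 118523626 to 118524025 (2.61-fold, 1.99 to 3.47) and chromosome 14 from 35321351 to 35321750 (2.92-fold, 2.18 to 4.00). Their reads rose from 67, 62 and 51 to 413, 405 and 373 before scaling to depth. The named lower SCL sites lay on chromosome 8 from 87225351 to 87225750 (0.438, 0.381 to 0.504), chromosome 1 from 182780901 to 182781300 (0.430, 0.371 to 0.498) and chromosome 8 from 125222976 to 125223375 (0.423, 0.364 to 0.490). Of these 3, the chromosome 1 site had an HA-RUNX1 site. FLI1 reads also fell at all 3, from 388 to 110, from 371 to 140 and from 407 to 83.

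FLI1 and SCL changed together at sites in the unions of both factors, which need a call in only 1 library of each pair. At 10916 sites common to both unions, 947 were higher for both factors, against 182 if the calls were independent, and 1995 were lower for both, against 1426. Opposite calls were made at 112 sites, against 1175. With the median ratio set to 1, 1220 sites were higher for both against 307, and 70 were opposite against 759. Across these sites, which are not independent replicates, the log2 ratios of FLI1 and SCL had a Pearson r of 0.683 and a Spearman rho of 0.557. The values of r were 0.735 at the 3712 sites with HA-RUNX1 and 0.447 at the 7204 without it. At HA-RUNX1 sites, exact read-start matches between induced FLI1 and induced SCL were 1.09 times those at 2 to 5 bp (44834 exact matches), and 1.02 times between the uninduced libraries. Whether fragments shared between the induced FLI1 and SCL libraries add to the joint change was not tested.

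Sites higher after induction were called in c-Kit progenitors more often than level-matched sites, and sites lower after induction less often. For FLI1, 10.3% (9.08 to 11.5) of higher sites had a c-Kit call, against 5.11% (4.34 to 5.999) of matched other sites. Lower FLI1 sites had 11.8% (11.3 to 12.4), against 20.3% (19.8 to 20.9), and with the median ratio set to 1 they had 5.48% (4.60 to 6.49), against 20.8%. For SCL, 21.1% (20.0 to 22.2) of higher sites had a c-Kit call, against 15.1% (14.2 to 16.0) matched, and 13.6% (12.6 to 14.7) of lower sites, against 22.4% (21.3 to 23.6). Without matching, other FLI1 sites had 11.7%, above the higher and close to the lower class, so the FLI1 differences under scaling to distinct reads rest on the matching. Other SCL sites had 19.5% (18.8 to 20.2), and at p of at most 1e-10 they had 22.8% against 20.3% of higher ones, so the result for higher SCL sites rests on the matching too. Mean c-Kit RPM at lower FLI1 sites were 0.555, against 0.740 at matched sites, and at lower SCL sites 0.695 against 0.991. The c-Kit libraries gave few sites, 3468 for FLI1 and 6047 for SCL, at the depth of the deepest libraries, and come from another ES line.

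**Figure D2:**
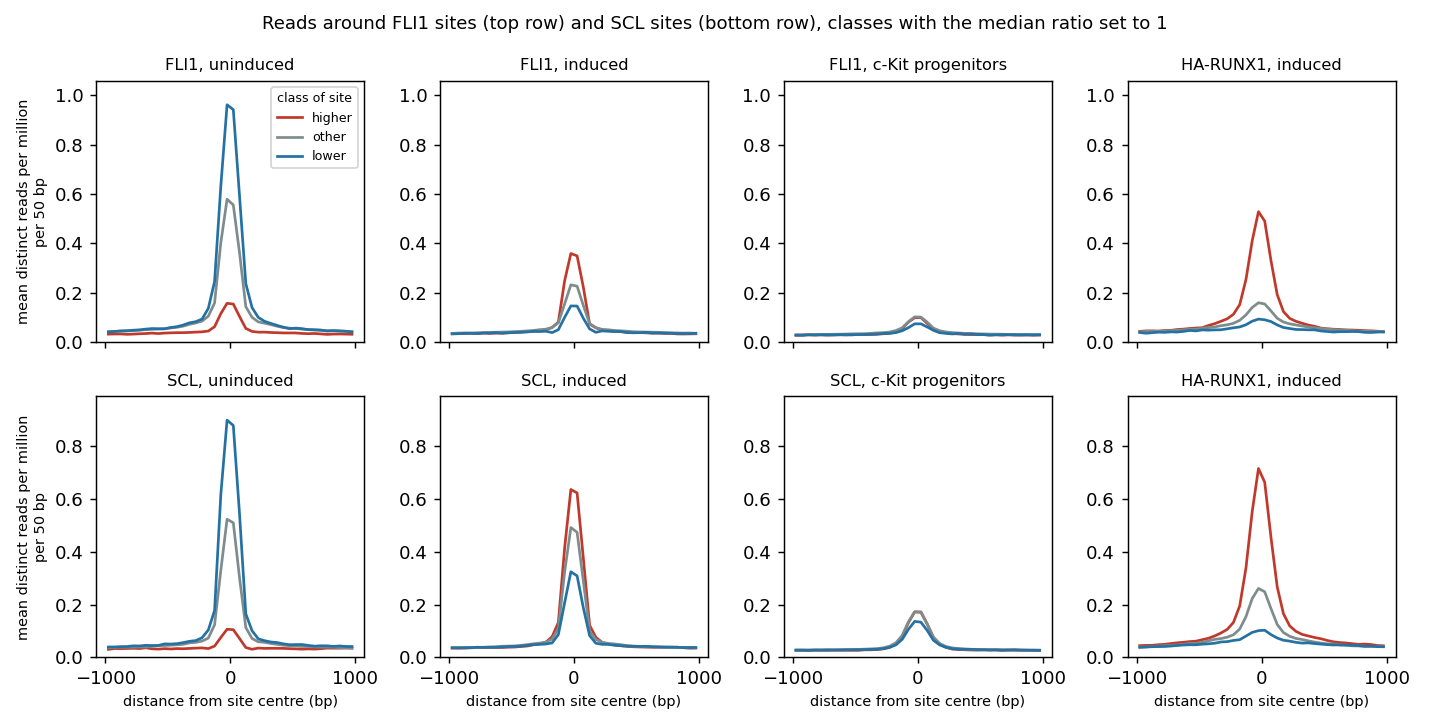
Mean RPM per 50 bp (vertical axes) against distance from the site centre in bp, for FLI1 sites (top row) and SCL sites (bottom row), with classes defined at a median ratio of 1. Each panel is 1 library and lines are the higher, other and lower classes. Anti-HA reads in induced cells are highest at the higher sites of both factors, which comprise 4820 FLI1 and 4839 SCL sites.

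H3K9Ac reads were higher in the induced library at nearly every called region. The induced library gave 16989 regions and the uninduced one 8645, and at equal depth 16989 and 8640. Over 17080 regions, 15175 were higher and 27 lower, with a median log2 ratio of 1.61. The regions called in each library held 30.2% of the induced and 6.91% of the uninduced reads. An HA-RUNX1 site lay in 54.7% (53.9 to 55.5) of higher regions, against 43.3% (42.6 to 44.0) of level-matched regions of class "other". Width was not matched: higher regions had a median of 2400 bp and other regions 1600 bp, and random shifts placed an HA-RUNX1 site in 6.91% and 4.67% of them. Relative to the common shift, with the median ratio set to 1, 180 regions were higher and 585 lower. Of those 180, 77.2% (70.4 to 83.1) held an HA-RUNX1 site, against 45.9% (38.9 to 53.3) of level-matched regions. Of the 585 lower ones, 20.0% (16.8 to 23.5) did, against 43.9% (39.5 to 47.9). Uninduced Pol II was called in 13.3% (8.73 to 19.2) of the 180, against 53.4% of level-matched regions, and in 60.7% (56.6 to 64.7) of the 585, against 40.8%. Of all other regions 72.3% had such a call, so the lower class lay below these and above its matched regions.

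The named higher H3K9Ac regions lay on chromosome 8 from 86720401 to 86729000 (2.78-fold, 2.65 to 2.92), chromosome 5 from 143574201 to 143586200 (2.70-fold, 2.56 to 2.84) and chromosome 17 from 34253201 to 34261600 (2.82-fold, 2.65 to 3.01). Each of these ratios is below the median of all regions. The named lower regions lay on chromosome 9 from 37208801 to 37210800 (0.482, 0.363 to 0.635), chromosome 16 from 3231601 to 3233200 (0.452, 0.334 to 0.606) and chromosome 18 from 4513401 to 4516000 (0.478, 0.350 to 0.648).

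C/EBPβ, a bZIP factor, gave 11472 sites in uninduced cells, and 16.6% (15.9 to 17.3) of them lay at an HA-RUNX1 site of induced cells. At sites with C/EBPβ and without HA-RUNX1, the median log2 ratio was -1.13 for FLI1, where sites with neither had -1.22, and -0.39 for SCL in both sets. Sites with both had -0.79 for FLI1 and 0.35 for SCL, below the -0.67 and 1.09 of all sites with HA-RUNX1. All FLI1 sites with C/EBPβ had -1.02, above all 10000 level-matched lists (-1.21 to -1.13). All SCL sites with C/EBPβ had -0.079, above the mean of their level-matched lists (-0.157) but inside the range of these lists (-0.238 to -0.068). H3K9Ac regions with C/EBPβ had 1.613, below the range of theirs (1.625 to 1.653). The 3 strongest C/EBPβ sites lay on chromosome 5 from 135484701 to 135485100 (43.1 RPM), chromosome 4 from 116792951 to 116793350 (42.0) and chromosome 2 from 50542801 to 50543200 (34.3). An HA-RUNX1 site was present at each. Pol II gave 17749 sites in uninduced cells, of which 23.8% (23.2 to 24.4) lay at an HA-RUNX1 site. The strongest were on chromosome 13 from 23831351 to 23831750 (29.1 RPM) and from 23713251 to 23713650 (29.0), and on chromosome 2 from 13495901 to 13496300 (26.5).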

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

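Keeping control sites at equal depth was chosen after seeing the data. Over the main counts and shares, 71 of the alternative values stayed within 1.5 times the count or within the interval and 36 did not, and of the secondary values 95 did, 102 did not and 3 reversed. Median log2 ratios were judged by a fixed difference instead. Some values could not move, such as pooled and median ratios under another fold rule and calls of a pair's shallower library at full depth. The cause of a move was not tested unless stated. At p of at most 1e-05 there were 4651 higher FLI1 and 6987 lower SCL sites, and at 1e-10 1514 and 2655. With duplicates kept, higher sites numbered 5130 for FLI1 and 9032 for HA-RUNX1, and 44 H3K9Ac regions were lower. With the median ratio set to 1, which moves every ratio of a pair by construction, higher and lower FLI1 sites were 4820 and 2334, H3K9Ac regions 180 and 585, and higher HA-RUNX1 sites 307. Scaling to reads outside called sites left 11 lower H3K9Ac regions. The 1.5-fold rule gave 51 lower H3K9Ac regions. Under the 3-fold rule, 7400 FLI1 and 1723 SCL sites and 5 H3K9Ac regions were lower, and 9119 H3K9Ac regions higher. In the union called at equal depth, 1715 HA-RUNX1 and 3044 SCL sites were higher, as fewer sites enter it, and full depth gave 46293 and 18483 induced sites. The share of higher FLI1 sites at HA-RUNX1 sites was 73.2% at 1e-10, 54.0% at a median ratio of 1, 60.2% within 50 bp and 75.6% within 1 kb. For SCL it was 63.1% at 1e-10, 56.7% within 50 bp and 74.7% within 1 kb, and for H3K9Ac 42.1%, where the p threshold removes HA-RUNX1 sites but no region, 77.2% at a median ratio of 1 and 58.0% within 1 kb. HA-RUNX1 sites with any uninduced call made up 18.8%, 16.9% (50 bp) and 25.7% (1 kb), and 19.8% of higher SCL sites had a c-Kit call within 50 bp. Reversed were the pooled FLI1 ratio at a median ratio of 1 (1.04), the median log2 SCL ratio at equal depth (-0.50) and the pooled SCL ratio with duplicates kept (1.02). The depth of 1302187 uninduced anti-HA reads limits calls at single HA-RUNX1 sites. Counts at promoters and of motifs, with their alternatives, were not run. No paired analysis was possible because each group has 1 library.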

Other observations

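The match of read starts of uninduced anti-HA outside called sites with its bound, the enrichment at sites far from HA-RUNX1 and the test of precipitation efficiency were chosen only after the result was seen. Chromosomes 8 and 14 were singled out after their values were seen. Outside called sites, read density on chromosome 8 was 0.987 to 0.997 times the library's median autosome in the 2 c-Kit libraries and 1.41 to 1.49 times in the 11 others, the ES input included. On chromosome 14 it was 0.909 to 0.916 times, against 1.26 to 1.32 times. The ratio of c-Kit to other libraries was 0.687 for chromosome 8 and 0.707 for chromosome 14, and 0.941 to 1.05 for the other autosomes. In bins of 1 Mb, the median ratio was 0.736 over the 126 bins of chromosome 8, 0.743 over the 119 bins of chromosome 14 and 1.06 over the 2136 bins of the other autosomes. Density on the Y chromosome was 0.674 to 0.735 times the median autosome in the c-Kit libraries and 0.00122 to 0.0489 times in the others, the highest being uninduced anti-HA with 60 reads outside sites. Chromosome X ranged from 0.390 to 0.394 in the c-Kit libraries and from 0.321 to 0.391 in the others. No explanation was tested.

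Higher FLI1 and SCL sites lay at HA-RUNX1 sites more often than other sites. The observed shares exceeded the upper bound of level-matched draws by 49.4 percentage points for FLI1 and 34.5 for SCL. This argues against selection by the mean read level of the induced and uninduced libraries. Level in the induced library alone was not matched, so selection by it stays open. Fragments carried from the induced anti-HA library are argued against by read starts: at higher sites with HA-RUNX1, exact minus offset (2 to 5 bp) matches were 0.0123 (-0.0255 to 0.0501, FLI1) and 0.0187 (-0.000113 to 0.0375, SCL) of those needed to supply the excess reads, taking the anti-HA duplicate share of 11.6% as the chance of a match. At all HA-RUNX1 sites the exact over offset ratio was 1.00 (FLI1) and 0.994 (SCL) times that of the uninduced libraries. Outside called sites the larger of both was 1.00 times the highest of the other libraries. That comparison leaves out uninduced anti-HA, which had a ratio of 1.44 with induced anti-HA. In the union called at equal depth 70.2% of higher SCL sites still lay at HA-RUNX1 sites, against 28.2% of other sites. This argues against the gap in depth at the calling step. Reads in these sites were still counted at full depth, so an effect of depth on the classes stays open. Gain of occupancy where induced RUNX1 binds and a difference between single cultures both stay open, since no test here separates them.

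Sites called in the uninduced anti-HA library lay at HA-RUNX1 sites of the induced library. Capture at all factor-bound sites alike is argued against: anti-HA over input was 1.03 (1.00 to 1.06) at the 58.6% of uninduced FLI1 sites and 1.05 (1.01 to 1.09) at the 60.0% of SCL sites far from HA-RUNX1, and 2.51 (2.33 to 2.71) and 2.53 (2.19 to 2.86) times as high at level-matched sites with HA-RUNX1. Capture at a subset of sites stays open, since the sites were split by anti-HA calls. Carry-over of fragments from the induced library met the bound set beforehand for excluding it, with exact over offset read-start matches at HA-RUNX1 sites 1.201 times those with induced FLI1 or SCL, under 1.5, but was kept open after a ratio of 1.44 was seen outside called sites, against 1.02 to 1.11 for the 11 other libraries, because a carried fragment matches only where the induced library also sequenced it. HA-RUNX1 made without doxycycline may also contribute: among HA-RUNX1 sites without another call, enrichment over input was 1.66 in the weakest 10%, fell to 1.38 and rose to 2.44 in the strongest 10%, 1.47 times (1.33 to 1.62) the weakest, so the comparison with the bound of 1.5 depends on the weakest sites.

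H3K9Ac reads were several-fold higher in the induced library at nearly all called regions. Scaling to reads outside called sites raised the median log2 ratio to 2.07. Called sites and regions of all libraries held 39.6% of the induced and 16.7% of the uninduced H3K9Ac reads, so this scaling could only raise the ratio. It therefore cannot decide whether scaling to distinct reads contributes. A higher efficiency of the induced precipitation may account for a common factor, and regions with and without an HA-RUNX1 site differed in median log2 ratio by 0.12, near the bound of 0.1 set for it. Against random lists of the same level, drawn from all regions, those with an HA-RUNX1 site had 1.66 against 1.63 (1.62 to 1.64). Both differences are far below the median of 1.61, and efficiency and a general rise of acetylation in induced cells cannot be told apart. With 1 library per condition, no value here separates them.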
